A study of Mus musculus with 15 samples.

How the data were processed

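RNA from CD8+ T cells of E.G7 tumours was measured in 15 libraries. The SMARTer ultra low input kit and Illumina HiSeq machines were used per the labels' protocols. The authors' bulk files give RPKM, reads per kilobase of transcript scaled to the mapped total, per the file headers, with 0.001 as the lowest value. The authors' other files give FPKM, fragments per kilobase scaled in the same way, per the file headers, rounded to 2 decimals with 0 as the lowest value. The labels name HISAT2, Bowtie2 and RSEM without versions and the build mm10, and they state neither filters nor annotation. No raw counts were used here, so count models were not run. Each library's group was taken from its title, because the strain and genotype fields of some libraries appear to count upward from one to the next.

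The files fall into 4 tables by the genes they list: 17205 unique symbols in the bulk pair, 15627 in the wild-type sorted libraries numbered 1, 17605 in those numbered 2 together with the libraries labelled KO, and 14710 in the antibody libraries. Symbols listed more than once were left out. The tables of the sorted libraries share 14020 symbols. The plan fixed before the data were examined counted a gene absent from a table as 0. Because the tables list different genes, the values reported rest instead on genes listed in every library of a fit, and counting absent genes as 0 became the alternative. Total reads of the bulk pair were estimated from the steps between low RPKM values. Of 3252 genes between the lowest values, 87.3% had a ratio between the libraries that was 1.086 times a fraction of whole numbers up to 12, within 0.02%, against 0.0923% after the ratio was shifted.

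Sorted populations were compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, over genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. By chance alone, 521 of 10411 genes or 509 of 10178 would have an unadjusted p under 0.05. The 3 population comparisons used the 6 wild-type libraries. The genotype comparison used all 9, with the population as a covariate, and a further model tested whether the genotype effect differed between populations. Replicate numbers were taken from the titles. The difference of number 2 minus number 1 correlated between populations at 0.193, 0.269 and 0.401 over 10411 genes, all over 0.1, so the numbers pair the wild-type libraries and a fit with the number as a block is given where it changes a call. The bulk pair and the antibody libraries have 1 library per group, so their ratios have no replicate check and no p-value. There a gene needed 5 or more in the higher library and a 2-fold ratio to be counted. The antibody effects were each read in 2 pairs of libraries with no library in common.

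Before the data were examined, 21 gene lists and a panel of 25 genes were fixed. The lists were effector molecules, inhibitory receptors, exhaustion regulators, naive and memory, effector differentiation, tissue residency, costimulatory receptors, cell cycle, glycolysis, oxidative phosphorylation, type I interferon response, immediate early and stress genes, chemokine and cytokine receptors, ribosomal proteins, T cell identity, and markers of myeloid, B, CD4 and regulatory T, NK, stromal and endothelial, and erythroid cells. Lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. In the unreplicated designs a list's median was placed among 10000 random lists matched on mean expression in 20 bins. Genes were named by a rule: the panel, the genes with the largest rises and falls past the threshold and in the same direction in every pair of libraries, the 8 largest ratios each way among genes at 10 or more in the unreplicated designs, and up to 4 members with the largest change in lists that passed or lay in the outer 2.5% on either side. Predicted genes, pseudogenes, small RNAs, histone genes and receptor variable segments were left out of the ranked parts. List members past the threshold adjusted over the list alone, and genes said to be chosen after their values were seen, stand outside it.

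The fits were tested on simulated data built on these libraries, with 50 genes changed at each size. Changed genes were drawn from those with a mean log2(FPKM + 1) of at least 4, and noise was drawn independently for each gene. The shares below therefore do not describe genes at lower values or differences that genes share between libraries. Of genes changed 16-fold, limma without a block called 48% between TIM-3_SP and DN, 34% between B7S1R_SP and DN and 36% between B7S1R_SP and TIM-3_SP, out of 10411 genes. For genes changed 4-fold these shares were 2%, 0% and 2%, and for 64-fold 94%, 96% and 98%. With the replicate block, 86%, 84% and 90% of the genes changed 16-fold were called. Of 10211 unchanged genes these 3 fits wrongly called 8, 4 and 8 without the block and 7, 7 and 11 with it. The genotype fit called 30% of genes changed 4-fold and 96% of those changed 16-fold, out of 10178. The list percentiles were tried instead on 6000 invented genes with independent differences and randomly drawn lists. There 1 of 40 unchanged lists lay in either outer 2.5% and a list shifted by 1.5 stood at 99.84. Lists whose genes move together are not covered by that trial.

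Alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean of at least 5, quantile normalization, equal upper quartiles, limma-trend, absent genes counted as 0, each library left out, the replicate block, all 9 libraries for the population comparisons, each wild-type set alone, and, in the unreplicated designs, a minimum of 1 and a 3-fold ratio. Coordinates come from GENCODE M21, on the same build as the labels name. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.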

Results

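CD8+ T cells were sorted on day 21 from E.G7 tumours, which grew from cells placed under the skin of mice. E.G7 is a T cell lymphoma line, derived from EL4, that makes ovalbumin (OVA). B7S1, encoded by Vtcn1, is a B7-family ligand that restrains T cells, and B7S1R is its receptor. The 15 libraries fell into 3 designs. Bulk OVA-specific CD8+ T cells gave 1 wild-type library and 1 library labelled B7S1 knockout (KO), with 6 mice per group. PD-1+ CD8+ T cells were parted by Tim-3, encoded by Havcr2, and by B7S1R into 3 populations. TIM-3_SP carried Tim-3 without B7S1R, B7S1R_SP carried B7S1R without Tim-3, and DN carried neither. Each population gave 2 wild-type libraries, numbered 1 and 2, and 1 library labelled KO. The last 4 libraries, with titles naming Control, anti_B7S1, anti_PD1 and combo, had 1 library each, and no dose or schedule was given.

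The total reads per library were not given. Step sizes of the lowest bulk values fitted 11100000 reads in the wild-type library and 12100000 in the library labelled KO. Depth behind the FPKM values is unknown. Genes at 1 or more numbered 8042 and 7908 in the bulk pair, 8860 to 10362 in the 9 sorted libraries, and 5752 in Control against 8640 in anti_PD1. Wild-type replicates of one population correlated across 10411 genes at 0.890 in DN, 0.761 in TIM-3_SP and 0.735 in B7S1R_SP, and genes are not independent replicates. Over all 9 sorted libraries, B7S1R_SP wild type numbered 1 correlated at 0.8229 with DN numbered 1 and 0.7285 with its replicate. TIM-3_SP wild type numbered 1 had 0.7755 and 0.7596 in the same order. DN labelled KO had 0.9496 with B7S1R_SP labelled KO and 0.8736 with DN wild type numbered 2. By contrast, DN wild type numbered 1 was closest to its replicate (0.8882), and TIM-3_SP numbered 2 to TIM-3_SP labelled KO (0.9463).

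Vtcn1, the gene targeted in the knockout, was not lower in any library labelled KO than in the wild-type library of the same table. In the bulk pair it stood at 0.0687 RPKM in the wild-type library and at 9.46 RPKM in the library labelled KO. Among the sorted libraries it was listed at 0 FPKM in all 3 wild-type libraries numbered 2. The libraries labelled KO held 0.16 FPKM in B7S1R_SP, 2.5 FPKM in TIM-3_SP and 1.02 FPKM in DN. The tables of the wild-type libraries numbered 1 and of the antibody libraries did not list it. Vtcn1 lies on chromosome 3 from 100825459 to 100896922 of mm10, and values per gene do not show which of its 6 distinct annotated exons the reads came from. The transcript therefore goes against the genotype labels or says nothing about them, and every genotype direction given here rests on those labels.

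Comparing TIM-3_SP with DN asks what marks tumour T cells that add Tim-3 to PD-1. TIM-3_SP cells held more transcript of the cytotoxic granule proteases Gzmb, Gzmd, Gzme and Gzmf and of the inflammatory chemokines Ccl3 and Ccl4. None of these genes passed in the main fit, which had no block. Gzma, another granzyme gene, changed side when 1 library was left out, to -0.66 without TIM-3_SP_WT replicate 1. Gzmf and Gzmd, 2 granzymes made by strongly activated killer cells, were higher in TIM-3_SP in both wild-type sets. Tcf7 and Id3, which encode transcription factors of stem-like T cells, and S1pr1, which encodes the receptor for exit from tissue, read lower in both wild-type sets, and none of the 3 passed over all genes, with or without a block. Havcr2, used in the sort, is no finding here.

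In limma, 0 of 10411 genes passed an adjusted p of 0.05 between TIM-3_SP and DN with unblocked libraries, and 358 had an unadjusted p under 0.05. With the replicate number as a block, 2 genes rose, both granzymes, and 654 had an unadjusted p under 0.05. Gzmf had a log2 fold change of 8.06 ± 0.76 (SE, blocked) and a limma adjusted p of 0.00525, against 0.326 without the block. Gzmd had 7.55 ± 0.75 and the same blocked adjusted p of 0.00525. Gzmf read 4.58 and 0 FPKM in the DN libraries and 1029 and 386 FPKM in TIM-3_SP. Gzmd, Gzme and Gzmf are close paralogs, so reads could not be assigned among them with certainty. Over 9 libraries with the replicate set as a block, Gzmb rose by 4.68 ± 0.50 (limma adjusted p = 0.0375). The other 5 genes called in that fit were Gzme, with Ccl4 (4.12 ± 0.52), Ccl3 (4.76 ± 0.59), Fcrl6 and Mrgprb3, chosen after their values were seen. Ccl4 and Ccl3 had an adjusted p of 0.0443. Gzmf and Gzmd lost the call there, at adjusted p-values of 0.105 and 0.139. Tcf7 had a log2 fold change of -3.66 ± 0.78 and Id3 of -4.69 ± 0.88, each lower in both sets with an adjusted p of 1. Pdcd1 differed by 0.54 ± 1.32, Lag3 by 0.63 ± 1.83 and Tox by -0.25.

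Of the gene lists, effector molecules rose between DN and TIM-3_SP with a median log2 fold change of 1.22 over 22 genes (camera adjusted p = 6.56e-09), but adjusted p = 0.531 with an estimated correlation. In that list 8 genes passed adjusted over the list alone and 0 adjusted over all genes, and with the replicate block 11 and 2. Naive and memory genes fell, with 22 of 23 lower and a median of -1.90 (camera adjusted p = 3.93e-13, and adjusted p = 0.531 with an estimated correlation). Here 5 genes passed adjusted over the list alone, among them Dapl1, Tcf7, Id3 and S1pr1, against 0 over all genes, and with the replicate block 10 and 0. Cell cycle genes rose by a median of 1.08 (camera adjusted p = 1.69e-09, and adjusted p = 0.531 with an estimated correlation), yet without TIM-3_SP_WT replicate 2 the median was 0.62 and the camera adjusted p 0.21. The type I interferon response fell by a median of -0.78 (camera adjusted p = 0.0108, and adjusted p = 0.992 with an estimated correlation). Its camera adjusted p was 0.256 without TIM-3_SP_WT replicate 1 and 0.423 without DN_WT replicate 1. In both of these lists 0 genes passed adjusted over the list alone and 0 over all genes. Inhibitory receptors had a median of 0.17 (camera adjusted p = 0.169) and exhaustion regulators one of -0.02 (0.75). With the replicate set as a block over 9 libraries, inhibitory receptors, a list that holds Havcr2, passed with a camera adjusted p of 0.00288, and adjusted p = 0.783 with an estimated correlation. So did exhaustion regulators, with 0.0289 and adjusted p = 0.881 with an estimated correlation, and effector differentiation, with 0.0103 and adjusted p = 0.783 with an estimated correlation.

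**Figure D1:**
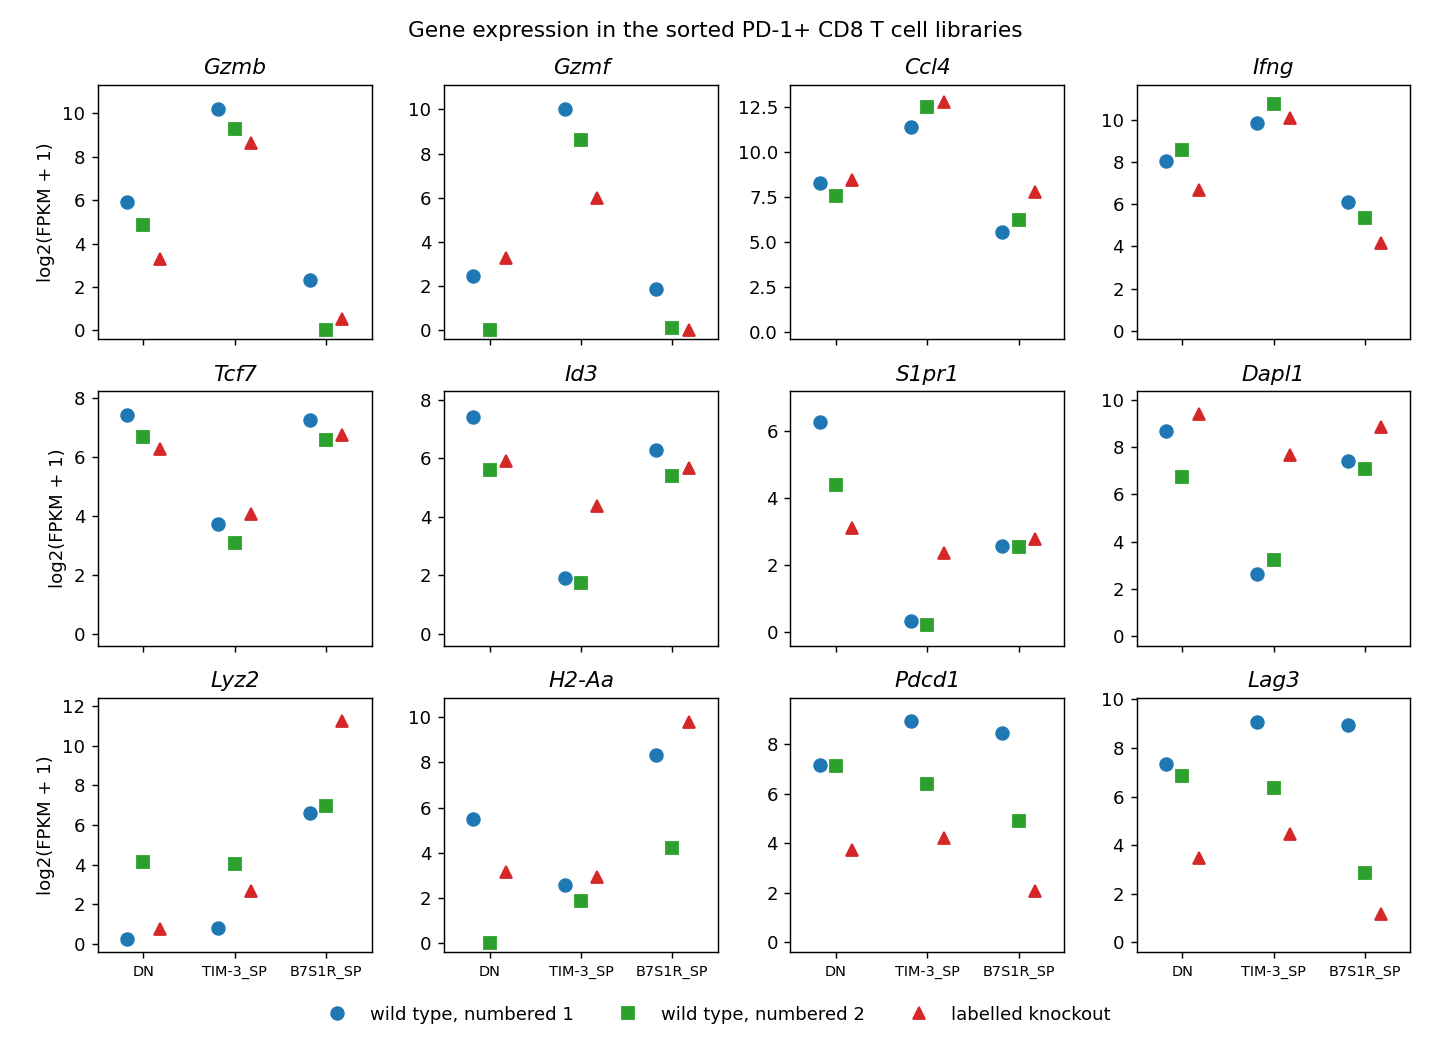
log2(FPKM + 1) of 12 genes on the y axis for the DN, TIM-3_SP and B7S1R_SP populations on the x axis. Each point is 1 library, and shape and colour give the wild-type library numbered 1, the one numbered 2 and the one labelled KO. Gzmb, Gzmf, Ccl4 and Ifng stand highest in TIM-3_SP, where Tcf7, Id3 and S1pr1 stand lowest.

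Comparing B7S1R_SP with TIM-3_SP sets the receptor-bearing cells against the Tim-3+ cells. In B7S1R_SP cells Gzmb, the main granzyme of killer cells, was far lower, and it passed with either block. Ifng was lower too, and passed with the block over 9 libraries but neither unblocked nor with the replicate block. Gzma read lower, but its log2 fold change was 0.75 without B7S1R_SP_WT replicate 1. Prf1, the pore former that delivers granzymes, was lower by an amount that depended on 1 library. Tcf7, a gene of memory-like T cells, was higher with the block over 9 libraries, while Id3 and Dapl1 read higher and passed over all genes neither unblocked nor with either block. B7S1R_SP libraries also held genes of macrophages and dendritic cells, among them the lysozyme gene Lyz2, the arginase gene Arg1 and the class II genes H2-Aa and H2-Eb1.

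Unblocked, limma called 0 of 10411 genes between B7S1R_SP and TIM-3_SP, with 493 at an unadjusted p under 0.05 and a smallest adjusted p of 0.150. With the replicate block, 1 gene rose and 6 fell, with 812 at an unadjusted p under 0.05. Gzmb had a log2 fold change of -8.56 ± 0.78 (SE, blocked; limma adjusted p = 0.00247), with 4.07 and 0 FPKM in B7S1R_SP against 1171 and 616 FPKM in TIM-3_SP. Gzmf (-8.33 ± 0.76), Gzmd (-7.68 ± 0.75) and Gzme (-6.83 ± 0.78) had blocked adjusted p-values of 0.00247, 0.00298 and 0.0106. The other called genes, chosen after their values were seen, were Ccl4 (-6.03 ± 0.80, blocked adjusted p = 0.0320), Serpina3f and Xlr3b. Over 9 libraries with the replicate set as a block, limma called 25 genes higher and 17 lower. In that fit Gzmb fell by 8.42 ± 0.50 (adjusted p = 0.00054), Id2 by 3.14 ± 0.45 (0.0373), and Tcf7 rose by 3.24 ± 0.45 (0.0327), while Ifng fell with an adjusted p of 0.00948. Without the block, Tcf7 had an adjusted p of 0.721, Ifng of 0.377 and Prf1 (-5.65 ± 1.77) of 0.956. Prf1 read 51.9 and 0 FPKM in B7S1R_SP, and its log2 fold change was -2.79 without B7S1R_SP_WT replicate 2. Lyz2 was 4.36 ± 1.45 higher on the log2 scale (adjusted p = 0.981), with 97.7 and 122.1 FPKM in B7S1R_SP against 0.76 and 15.4 FPKM in TIM-3_SP.

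Effector molecules fell from TIM-3_SP to B7S1R_SP by a median of -2.83 (camera adjusted p = 1.48e-15, and adjusted p = 0.327 with an estimated correlation). Of them 14 passed adjusted over the list alone and 0 over all genes, and with the replicate block 15 and 5. Inhibitory receptors fell by a median of -1.73 (camera adjusted p = 6.65e-08, and adjusted p = 0.734 with an estimated correlation), with Havcr2 and Cd244 past the threshold adjusted over the list alone and 0 genes over all genes. Havcr2, used in the sort, stayed in the tested list and is no finding here. Naive and memory genes rose by a median of 1.39 (camera adjusted p = 0.00016, and adjusted p = 0.734 with an estimated correlation), with 4 genes past the threshold adjusted over the list alone and 0 over all genes. Without TIM-3_SP_WT replicate 2 this median was 0.97 and its camera adjusted p 0.0656. Myeloid markers rose by a median of 2.26 (camera adjusted p = 1.04e-05, and adjusted p = 0.314 with an estimated correlation), with 17 of 20 genes higher. In this list and in the 5 lists that follow, 0 genes passed adjusted over the list alone and 0 over all genes without the block. With it 11 myeloid genes passed over the list alone. T cell identity fell by a median of -0.93 (camera adjusted p = 0.00138, and adjusted p = 0.734 with an estimated correlation). Without B7S1R_SP_WT replicate 2 its median was -0.12 and its camera adjusted p 0.293, and without TIM-3_SP_WT replicate 2 the latter was 0.076. Effector differentiation (-1.08, camera adjusted p = 0.000881) also fell, but had adjusted p = 0.734 with an estimated correlation. Exhaustion regulators (-0.61), costimulatory receptors (-0.74) and the cell cycle (-0.35) fell with camera adjusted p-values of 0.00996, 0.00996 and 0.0319, each with adjusted p = 0.802 with an estimated correlation. All 3, and effector differentiation, lost the call without B7S1R_SP_WT replicate 2, where their medians were 0.57, 0.41, -0.23 and 0.17. Without TIM-3_SP_WT replicate 2 the camera adjusted p was 0.279 for costimulatory receptors, 0.503 for the cell cycle and 0.076 for effector differentiation, and without TIM-3_SP_WT replicate 1 it was 0.224 for exhaustion regulators. Immediate early and stress genes (-0.31) had a camera adjusted p of 0.0594 unblocked and 0.0299 with the replicate block, there with adjusted p = 0.721 with an estimated correlation.

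**Figure D2:**
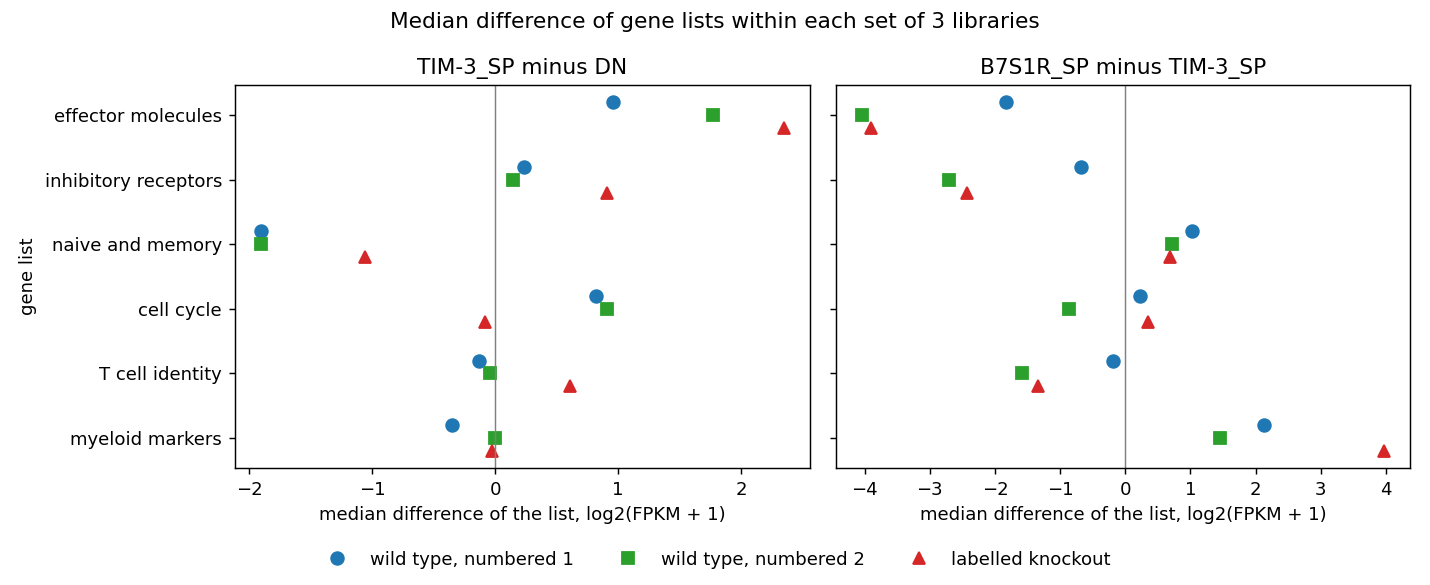
Median difference in log2(FPKM + 1) on the x axis for 6 gene lists on the y axis, TIM-3_SP minus DN on the left and B7S1R_SP minus TIM-3_SP on the right. Each point is the median within 1 set of 3 libraries (wild type numbered 1, wild type numbered 2, labelled KO), and the vertical line marks 0. Effector molecules lie above 0 on the left and below 0 on the right in all 3 sets.

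Comparing B7S1R_SP with DN asks what the receptor marks among PD-1+ Tim-3- cells. Gzmb and Ifng, genes of killing and of the main T cell cytokine, read lower in B7S1R_SP than in DN in both wild-type sets, and neither passed. Lyz2, Arg1, H2-Ab1 and H2-Aa, genes of myeloid cells, read higher, and none of the 4 passed over all genes, with or without the replicate block. In limma 0 of 10411 genes passed, both unblocked (280 at an unadjusted p under 0.05) and with the replicate block (553). Gzmb had a log2 fold change of -4.23 ± 1.00, Ifng of -2.57 ± 0.79, Ctla4 of -2.11 ± 1.13 and Tcf7 of -0.14 ± 0.78, each with an adjusted p of 1. Without B7S1R_SP_WT replicate 2, Ctla4 had -0.57. Lyz2 had 4.59 ± 1.45 with the same adjusted p.

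Of the lists, 15 passed in camera between B7S1R_SP and DN, all 15 with adjusted p-values from 0.268 to 0.644 with an estimated correlation. Without B7S1R_SP_WT replicate 2 the number passing was 3, and without DN_WT replicate 1 it was 8. Of the 15, myeloid markers and the cell cycle alone passed without B7S1R_SP_WT replicate 2. Myeloid markers rose by a median of 1.99 (camera adjusted p = 7.36e-06, and adjusted p = 0.268 with an estimated correlation). Inhibitory receptors fell by a median of -1.26, with 19 of 20 lower (camera adjusted p = 7.82e-06, and adjusted p = 0.502 with an estimated correlation), but without B7S1R_SP_WT replicate 2 the median was -0.28 and the camera adjusted p 0.235. Effector molecules (-1.08), tissue residency (-1.38), costimulatory receptors (-1.08), naive and memory (-1.004), effector differentiation (-1.10), T cell identity (-0.94) and the type I interferon response (-0.74) also had lower medians, and each had adjusted p = 0.502 with an estimated correlation. Without B7S1R_SP_WT replicate 2 the median was -0.73 for effector molecules, -0.60 for tissue residency, 0.17 for costimulatory receptors, -0.30 for naive and memory, -0.02 for effector differentiation, -0.32 for T cell identity and -0.21 for the type I interferon response. Without DN_WT replicate 1 it was -0.34 for naive and memory and -0.33 for the type I interferon response. Exhaustion regulators (-0.63), immediate early and stress genes (-0.85) and chemokine and cytokine receptors (-0.52) had lower medians and adjusted p = 0.636 with an estimated correlation. Without B7S1R_SP_WT replicate 2 these 3 medians were 0.41, 0.13 and 0.86, and the last list also lost its call without TIM-3_SP_WT replicate 1 (camera adjusted p = 0.0614) or replicate 2 (0.0909). The cell cycle (0.72) and glycolysis (0.68) had higher medians with adjusted p = 0.502 with an estimated correlation, and oxidative phosphorylation (0.38) had adjusted p = 0.644 with an estimated correlation. The oxidative phosphorylation median turned to -0.27 without B7S1R_SP_WT replicate 2. Without DN_WT replicate 1 the cell cycle median was 0.13 and its camera adjusted p 0.301. In every one of these lists 0 genes passed adjusted over the list alone and 0 over all genes without the block. With the replicate block Gzmb and 10 myeloid genes passed over the list alone, among them H2-Ab1, H2-Aa, Lyz2 and Arg1.

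The genotype comparison in the sorted cells asks what loss of B7S1 in the host changes in PD-1+ T cells. Genes of the inhibitory receptors Pdcd1, Lag3, Tigit and Ctla4 read lower in the libraries labelled KO, as did the exhaustion-linked transcription factor genes Tox, Eomes and Bhlhe40. Junb, Dusp1, Ppp1r15a and Egr1, which respond early to T cell receptor signals and stress, read lower on the average over both wild-type sets. Dapl1, a gene of memory-like cells, read higher. The libraries labelled KO shared their table with the wild-type libraries numbered 2, and the size of the difference depended on which wild-type set they were held against.

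In limma 0 of 10178 genes passed between KO and wild type, with 1377 at an unadjusted p under 0.05, a smallest adjusted p of 0.182 and a median log2 fold change of all genes of -0.41. Against the wild-type libraries numbered 1 alone, 195 genes were called higher and 1043 lower. Against those numbered 2 alone, limma called 4 lower and 0 higher, with 1255 at an unadjusted p under 0.05. These 4, named after their values were seen, were Xkrx (-6.57 ± 0.48, adjusted p = 0.0182) and the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs. Pdcd1 had a log2 fold change of -3.83 ± 0.82 over both sets (adjusted p = 0.339). It read 136.6 FPKM in the DN wild-type library numbered 2 against 12.1 in the one labelled KO, 83.8 against 17.7 in TIM-3_SP, and 28.5 against 3.17 in B7S1R_SP. Lag3 (-3.85 ± 1.17), Tigit (-2.41 ± 0.67), Ctla4 (-2.62 ± 0.73), Tox (-1.81 ± 0.52) and Dapl1 (2.69 ± 0.68) each had an adjusted p of 0.339. Gzmb differed by -1.29 ± 0.61 (0.375), Ifng by -1.13 ± 0.47 (0.36) and Tcf7 by -0.09 ± 0.46. No gene passed for a genotype effect that differed between populations, and the smallest limma adjusted p was 0.999993. There 45 of 10178 genes had an unadjusted p under 0.05, against 509 expected by chance. The spread in that test came from the wild-type replicates alone, which differed between the sets, so a uniform effect is not shown.

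Between genotypes 14 lists passed in camera, every one with adjusted p = 0.428 with an estimated correlation, and 9 passed without B7S1R_SP_KO replicate 1. Exhaustion regulators fell by a median of -1.31, with all 19 lower on the average over both sets (camera adjusted p = 0.000154, and adjusted p = 0.428 with an estimated correlation). Of these Bhlhe40, Tox, Ikzf3 and Eomes passed adjusted over the list alone and 0 genes over all genes. Inhibitory receptors fell by a median of -1.45 (camera adjusted p = 0.000627, and adjusted p = 0.428 with an estimated correlation), and 5 of them passed adjusted over the list alone against 0 over all genes. Immediate early and stress genes fell by a median of -1.63 (camera adjusted p = 5.93e-07, and adjusted p = 0.428 with an estimated correlation), with 13 past the threshold adjusted over the list alone and 0 over all genes. Oxidative phosphorylation rose by a median of 1.04 (camera adjusted p = 9.67e-16) and ribosomal proteins by 0.67 (1.02e-11), both with adjusted p = 0.428 with an estimated correlation. In these 2 lists 0 genes passed adjusted over the list alone and 0 over all genes. These medians depended on the wild-type set. Against the libraries numbered 1 alone they were -1.92 for exhaustion regulators, -1.96 for inhibitory receptors, -2.25 for immediate early and stress genes and 1.51 for oxidative phosphorylation. Against those numbered 2 alone they were -0.68, -0.69, -0.95 and 0.61, with 4 inhibitory receptors and 0 genes of the other 3 lists past the threshold adjusted over the list alone. Within that table, DN had -1.54 for exhaustion regulators, -2.09 for immediate early and stress genes and 1.25 for oxidative phosphorylation. TIM-3_SP had -0.35, -0.64 and 0.36, and B7S1R_SP had -0.13, -0.19 and 0.21. The cell cycle (0.42) and myeloid markers (0.60) also rose, while costimulatory receptors (-1.70), effector differentiation (-1.30), glycolysis (-0.91), chemokine and cytokine receptors (-1.16), T cell identity (-1.04), effector molecules (-1.19) and CD4 and regulatory T cell markers (-1.59) fell, all with adjusted p = 0.428 with an estimated correlation. In these 9 lists Gzme, Aldoa, Il1r2, Il10ra, Ctla4 and Il2ra passed adjusted over the list alone, and 0 genes over all genes. Their medians too depended on the wild-type set. Against the libraries numbered 2, DN, TIM-3_SP and B7S1R_SP had cell cycle medians of 0.33, -0.41 and 0.65. In the same order, costimulatory receptors had -1.41, -0.50 and -0.33, and effector molecules -0.86, -0.01 and -0.16. Chemokine and cytokine receptors had -1.25, -0.35 and 0.05. Without B7S1R_SP_KO replicate 1 the myeloid median was -0.36, and the camera adjusted p was 0.108 for effector molecules, 0.108 for effector differentiation, 0.0731 for glycolysis and 0.192 for CD4 and regulatory T cell markers. For effector molecules it was also 0.0535 without B7S1R_SP_WT replicate 1, 0.0575 without DN_WT replicate 1 and 0.0959 without TIM-3_SP_WT replicate 2. Without B7S1R_SP_WT replicate 2 it was 0.0839 for CD4 and regulatory T cell markers and 0.0519 for glycolysis. Naive and memory genes did not pass over both sets, with a median of -0.01 and a camera adjusted p of 0.195. Against the wild-type libraries numbered 2 alone they had a median of 0.40 (0.00268, and adjusted p = 0.529 with an estimated correlation).

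The bulk pair asks the same of OVA-specific CD8+ T cells, with 1 library on each side, so no p-value was drawn. The library labelled KO held more Ifng, Ccl3 and Ccl4, the cytokine and chemokines of stimulated killer cells, and more Gzmk, while the effector genes Gzma and Gzmd and the memory-linked genes Ccr7 and Dapl1 were lower. The mitotic genes Ccnb2, Aurka, Aurkb and Ccnb1 and the antiviral genes Ifit1, Oas3, Bst2 and Rtp4 were higher. Aurkb reached only 4.45 RPKM. Ccnb2 and Aurka stood at 0.117 and 0.047 RPKM in wild type, where 1 read on a 1 kb transcript gives about 0.09 RPKM. Of 33 measured cell cycle genes 23 were higher and 10 lower, with Ccne1 going from 12.2 to 4.97 RPKM. Of 18 interferon response genes 13 were higher and 5 lower, with Ifit3 going from 3.38 to 0.75 RPKM. The inhibitory receptor genes Pdcd1, Havcr2 and Tigit were somewhat higher, and Lag3 and Ctla4 somewhat lower. Each of these ratios, like that of Ifng, was under 2-fold. With equal upper quartiles the log2 ratio was 0.39 for Pdcd1, 0.28 for Havcr2, 0.03 for Tigit, -0.68 for Lag3 and -0.70 for Ctla4. Ifng stood at 487 RPKM in the wild-type library and 907 RPKM in the library labelled KO, Pdcd1 at 77.8 and 120.7 RPKM, and Gzmb at 945 and 784 RPKM. Ccl4 and Ccl3, chosen after their values were seen, stood at 5573 and 1184 RPKM in wild type against 14264 and 3249 RPKM. Ccr7 fell from 893 to 131 RPKM across the pair, Tbx21 from 7.24 to 2.67 RPKM and Eomes from 3.55 to 0.956 RPKM.

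Among 6075 genes at 5 RPKM or more in the higher bulk library, 651 were at least 2-fold higher and 738 at least 2-fold lower in the library labelled KO. With equal upper quartiles, which moved the median log2 ratio of all genes to -0.23, these counts were 459 and 1043. The largest ratios in the naming rule included Ccnb2, a mitotic cyclin, from 0.117 to 33.8 RPKM, Gzmm, a granzyme, from 0.0701 to 10.4 RPKM, and Chaf1b, Galk1, Mettl21a, Fabp4, Msrb2 and Lenep on the higher side. On the lower side were Tmem251, from 89.0 to 1.997 RPKM, Klrg1, a receptor of terminal effector cells, from 14.2 RPKM to the lowest value of 0.001, and Coprs, Gstm5, Blvrb, Acbd7, Fkbp7 and Rpl39l. Against 10000 matched random lists, the interferon response stood at percentile 99.65 (median log2 ratio 0.62) and the cell cycle at 99.49 (0.39). Naive and memory genes stood at 0.66 (-0.53) and ribosomal proteins at 1.36 (-0.17). Effector molecules (-0.19, percentile 4.02), inhibitory receptors (0.18, 87.7) and exhaustion regulators (0.15, 77.5) lay in neither outer 2.5%.

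Bulk and sorted genotype differences had little in common gene by gene. Pdcd1 and Tox, lower in the sorted libraries labelled KO, were higher in the bulk one by less than 2-fold. Across 7233 genes Pearson's r was 0.0582 and Spearman's rho 0.0490, with 51.1% of genes on the same side, and genes are not independent replicates. With the wild-type libraries numbered 2 alone, r was 0.0067.

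The antibody libraries allow each antibody to be read in 2 pairs that share no library. The PD-1 antibody was read as anti_PD1 over Control and as combo over anti_B7S1, the B7S1 antibody as anti_B7S1 over Control and as combo over anti_PD1. With PD-1 antibody, genes of DNA synthesis and mitosis such as Rrm2 and Ccna2 and the granzyme gene Gzmk were higher, and the genes of naive and memory-like cells S1pr1, Id3 and Tcf7 were far lower. Ccna2 was listed at 0 FPKM in both libraries without the antibody and stood at 195 and 232 FPKM with it. Gzmk was likewise at 0 without it and at 137 and 134 FPKM with it. A value of 0 does not show absence here, since Control listed 42.4% of its genes at 0, among them Ndufv2, a gene of respiratory complex I that read 19.2 to 42.7 FPKM in the other 3. S1pr1 stood at 90.8 FPKM in Control and 0.07 in anti_PD1, and at 120.2 in anti_B7S1 and 0.02 in combo. Tcf7 stood at 73.8 and 9.96 FPKM in the first pair and at 85.2 and 2.5 FPKM in the second. Spp1, the osteopontin gene, was the largest rise in the naming rule, from 0.13 to 972 FPKM and from 0.04 to 2971 FPKM. The cell cycle list stood at percentile 100 in both pairs (median log2 ratios 5.74 and 3.84). Effector molecules stood at 100 and 99.07 (3.23 and 0.76), effector differentiation at 98.03 and 99.6 (1.60 and 1.21), and naive and memory genes at 0 and 0 (-2.39 and -3.30). Of 6255 genes at 5 FPKM or more in both pairs, 978 were at least 2-fold higher and 456 at least 2-fold lower in both, against 802 and 375 if the pairs were independent. With equal upper quartiles the first 2 counts were 1081 and 324, and with quantile normalization 865 and 591. Genes that went opposite ways by at least 2-fold numbered 1158, against 1135 if independent. Across genes the ratios of the pairs had a Pearson's r of 0.095. The median log2 ratio of all genes was 0.39 in the first pair and 0 in the second.

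The B7S1 antibody left little that held in both pairs. Pdcd1, the PD-1 gene, and Il7r, the receptor gene for the survival cytokine IL-7, were higher in both. Glycolysis genes had a lower median in both. Pdcd1 stood at 117 FPKM in Control and 510.0 in anti_B7S1, and at 292 in anti_PD1 and 734.5 in combo, log2 ratios of 2.11 and 1.33. Il7r had log2 ratios of 1.27 and 1.40, and Tox of 1.98 and 0.79. With equal upper quartiles the second ratio was under 2-fold for Pdcd1 (0.82), Il7r (0.91) and Tox (0.28). Gzmb, Prf1 and Havcr2 were near 0 in Control alone, at 0.04, 0.11 and 0.19 FPKM, and at 788, 295 and 174 FPKM in anti_B7S1. Ribosomal proteins stood at percentile 99.99 in the first pair and 0.25 in the second. Glycolysis was the 1 list in the same outer 2.5% of both pairs, at percentiles 0.665 (median -0.67) and 0.065 (-0.96). The interferon response stood at 99.97 (3.96) and 91.06 (0.40). Of 5963 genes, 496 were at least 2-fold higher and 503 at least 2-fold lower in both pairs, against 440 and 457 if independent. With equal upper quartiles the first 2 counts were 366 and 565. A further 1101 went opposite ways, against 941. The ratios of the pairs had a Pearson's r across genes of -0.01. Scamp2 and Galm headed the genes higher in both pairs, and Ube2t and Chaf1b those lower.

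**Figure D3:**
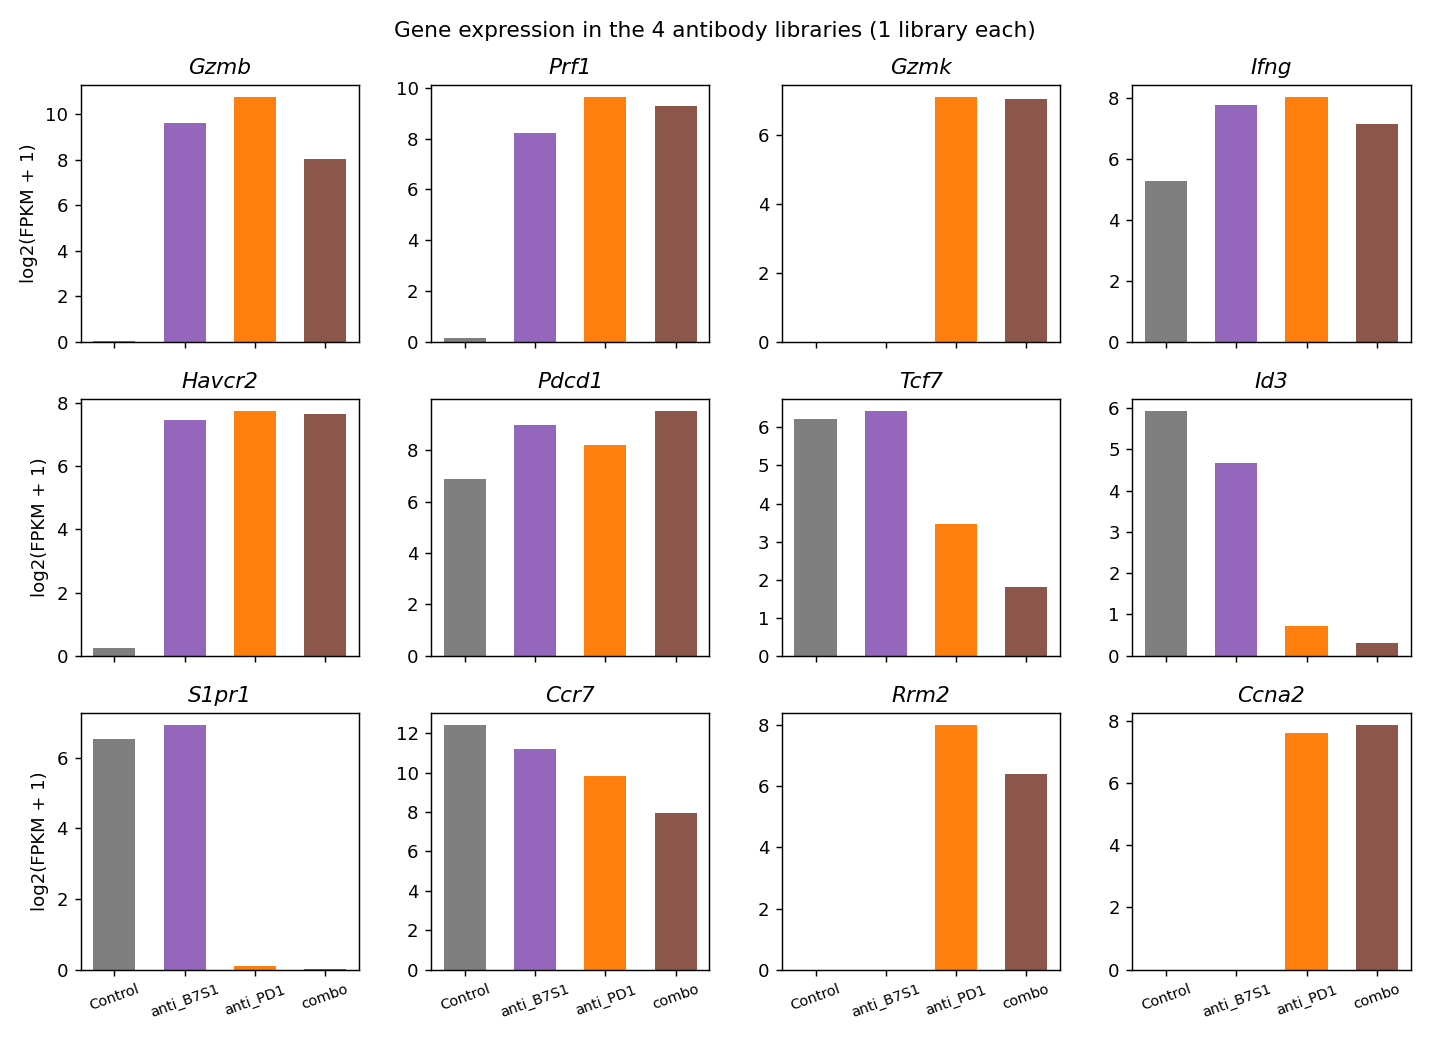
log2(FPKM + 1) of 12 genes on the y axis in the Control, anti_B7S1, anti_PD1 and combo libraries on the x axis. Each bar is 1 library and starts at 0. Gzmk, Rrm2 and Ccna2 stand highest in anti_PD1 and combo, where Id3 and S1pr1 are near 0.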

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

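The tests of exchanged labels, the chromosomal region, carried-over myeloid RNA, preparations, the T cell share, haemoglobin and other splits of the libraries were chosen only after the result was seen.

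In the antibody libraries, 3 panel genes moved one way in one pair and the opposite way in the other pair for the same antibody, each by at least 2-fold, and the differences were not tested. Gzmb, the main granzyme, had a B7S1 antibody log2 ratio of 9.57 over Control and of -2.74 on top of PD-1 antibody. Ctla4, an inhibitory receptor gene, had 3.07 over Control and -1.39 on top of PD-1 antibody. For the PD-1 antibody, Gzmb had 10.69 over Control and -1.61 on top of B7S1 antibody, Ctla4 had 2.53 and -1.94, and the chemokine gene Ccl5 had 1.505 and -1.31. The share of genes listed at 0 was 42.4% in Control, 30.07% in anti_B7S1, 15.25% in anti_PD1 and 32.82% in combo. With 1 library per treatment, no explanation was tested.

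Vtcn1 was higher in libraries labelled KO than in the wild-type library of the same table. Raised transcription of the whole region is argued against by a median bulk log2 ratio of 0.10 over the 8 expressed coding genes within 1 Mb. Their ratios ran from -1.09 for Ttf2 to 2.20 for Slc22a15, so a change of single neighbours is not covered. Transcript of the targeted allele outside the deleted part stays open, since 0 libraries have values per exon. So do labels exchanged, in the bulk pair alone or in every table: in 3 of 3 sorted populations Vtcn1 was above 0 in the library labelled KO and listed at 0 in the wild-type one numbered 2, but this is part of the pattern itself and as low as 0.16 FPKM.

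Myeloid genes were high in B7S1R_SP, above all in the library labelled KO, where Lyz2 stood at 2440 FPKM, H2-Aa at 870.8 and C1qb at 587. A general rise of weakly expressed genes is argued against, since the myeloid median stood at percentile 100 among matched random lists in each of the 3 sets. RNA of carried-over myeloid cells is a candidate explanation left open: the myeloid median was above 1 with T cell identity in the lower outer 2.5% of random lists in 2 of 3 sets, B7S1R_SP minus TIM-3_SP, while among the wild-type libraries numbered 1 T cell identity had -0.19 at percentile 14.83. The sort for CD8 should remove such cells, and of the 30 markers 3 are also in other lists and 20 reached 1 FPKM in a TIM-3_SP or DN wild-type library. Cd8a, however, read lower in wild-type B7S1R_SP than in TIM-3_SP, with log2 fold changes from -3.10 to -0.44 when 1 library was left out. Against DN they ran from -2.87 to -0.21, so the sort alone does not decide the question. Expression by the sorted B7S1R+ T cells themselves stays open, since 0 libraries hold single cells.

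Inhibitory receptor genes such as Pdcd1 and Lag3 read lower in the sorted libraries labelled KO. A difference between preparations, which the labels do not name, cannot be told apart, since the list medians of wild type numbered 2 minus numbered 1 were -0.22 in DN, -0.64 in TIM-3_SP and -2.15 in B7S1R_SP, those of KO minus numbered 2 were -2.26, -0.33 and -0.21, and the former were the larger in 2 of 3 populations. Haemoglobin RNA in the wild-type libraries numbered 2 was left undecided: taking it out brought the difference closer to 0 in 0 populations, but it can only lower the libraries labelled KO against them. A smaller share of T cell RNA cannot be told apart, because naive and memory genes were higher while T cell identity was lower in only 2 of 3 populations. Cd8a had log2 fold changes from -1.63 to -0.90 between KO and wild type when 1 library was left out. An effect of B7S1 loss stays open as well.

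With 0 genes called by genotype, each of the 81 estimable splits of the 9 libraries into 3 and 6 reaches that count by construction (81 of 81), which says nothing, and the highest other split called 2104. Chance cannot be excluded for the 1377 genes at an unadjusted p under 0.05, since 13 of the 81 splits gave at least as many, the highest other giving 3909, and so did 3 of the 27 splits that take 1 library from each population. That highest split set the 3 wild-type libraries numbered 1 apart, which points to a structure of the libraries that no label names, while setting those numbered 2 apart gave 231. Against the wild-type libraries numbered 2, which share their table, limma called 4 genes.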

How the results depend on the processing

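The alternatives without the B7S1R_SP libraries, the settings applied to list tests and the agreement with the wild-type libraries numbered 2 alone were chosen after seeing the data. For counts of genes and lists and the agreement, 156 of 192 alternative values stayed on the same side and within 1.5 times the main value. Main gene counts in the sorted populations were 0, and counts that stayed at 0 are among these, which does not show that a result held. In the sorted populations 14 counts were larger and 12 smaller by more than that. In the unreplicated designs and the agreement 10 values moved by more than that. Of 811 list results under alternatives, 687 kept the camera direction and the threshold, 115 lost the threshold and 9 reversed in camera direction. Some medians changed sign while the camera direction held. Between B7S1R_SP and TIM-3_SP without B7S1R_SP_WT replicate 2, costimulatory receptors had 0.41 and effector differentiation 0.17, both below 0 in the main fit. Of 1117 values for panel genes in the sorted populations, 1083 kept their side, 23 passed the threshold anew and 11 reversed. For panel genes 6 of 24 values moved in the bulk pair and 8 of 64 in the antibody libraries. The cause was not tested in any of these.

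With the replicate block, limma called 2 genes between TIM-3_SP and DN and 7 between B7S1R_SP and TIM-3_SP. Over 9 libraries the block gave 6 and 42 genes, and 7 lists for TIM-3_SP against DN. Of the list calls it added immediate early and stress genes between B7S1R_SP and TIM-3_SP. A pseudocount of 5 gave 3 and 5 genes, all 9 libraries with genotype as a covariate 1 and 12, and limma-trend 6 between B7S1R_SP and TIM-3_SP. With an estimated correlation 0 lists passed in each of the 4 comparisons, and with fry 0 unblocked. With the replicate block fry gave naive and memory genes adjusted p-values of 0.0128, 0.0405 and 0.0338 in the 3 population comparisons, and over 9 libraries effector molecules 0.0116 between B7S1R_SP and TIM-3_SP. Against the wild-type libraries numbered 1 alone, fry passed 4 genotype lists, the smallest adjusted p being 0.00859.

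For genotype, the wild-type libraries numbered 1 alone gave 1238 genes, those numbered 2 alone 4, and these without B7S1R_SP 10. Without the B7S1R_SP libraries 9 lists passed, and the myeloid median was -0.49, or -0.28 without the libraries numbered 1 as well. The agreement with the bulk pair was 0.0067 with the libraries numbered 2 alone.

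In the bulk pair, a pseudocount of 5 gave 318 higher and 387 lower genes, a minimum of 1 gave 1154 and 1296, and a 3-fold ratio 276 and 325. With a 3-fold ratio, the B7S1 antibody had 283 genes higher and 333 lower in both pairs, and the PD-1 antibody 264 lower.

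Leaving out 1 library, genotype calls ranged from 0 to 1, the 1 without DN_WT replicate 1, and genotype lists from 9 to 15. Lists between B7S1R_SP and DN ranged from 3 to 16. For that comparison the medians ranged from -1.94 to 0.41 for exhaustion regulators, -0.27 to 1.05 for oxidative phosphorylation, -1.83 to 0.13 for immediate early genes and -1.67 to 0.86 for chemokine receptors, Lag3 from -4.23 to 1.86, Tbx21 from -2.92 to 0.69 and Prf1 from -4.95 to 0.78. Between B7S1R_SP and TIM-3_SP the ranges were -1.84 to 0.57 for exhaustion regulators, -1.03 to 0.069 for the cell cycle, -4.85 to 1.23 for Lag3, -3.75 to 0.0837 for Tbx21 and -3.85 to 0.75 for Gzma. Between TIM-3_SP and DN, Gzma ranged from -1.15 to 4.30 and Tnf from -2.34 to 0.30. The genotype median of myeloid markers ranged from -0.36 to 1.10. A lone library left in a group was taken to vary like the others. FPKM without totals leaves the depth, and what low values could show, unknown.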

Other observations

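The genes below were chosen after their values were seen, and against the wild-type libraries numbered 2 alone limma called Xkrx (adjusted p = 0.0182) and neither Penk nor Igfbp6. In the table that holds the wild-type libraries numbered 2 and the libraries labelled KO, 119 genes were at least 2-fold lower and 43 at least 2-fold higher in the KO library of all 3 populations, among 5885 genes with a mean of 5 FPKM or more. The numbers expected from such pairs of single libraries were not estimated. The lower genes included haemoglobin genes such as Hba-a1 and Hbb-bs, and the median log2 fold change of all genes against these wild-type libraries was -0.157. Penk, which encodes an opioid precursor that T cells make after activation, was among the lower ones. It stood at 1058 and 97.9 FPKM in DN, 617.5 and 30.1 FPKM in TIM-3_SP, and 467 and 39.8 FPKM in B7S1R_SP, wild type before KO. Xkrx, a gene of the XK family of membrane proteins, went from 233 to 0.1 FPKM in DN, 56.7 to 0.03 in TIM-3_SP and 81.2 to 0.14 in B7S1R_SP. Igfbp6, which encodes a binding protein for insulin-like growth factors, was higher in the libraries labelled KO, at 632 against 1.22 FPKM in DN, 73.7 against 3.35 in TIM-3_SP and 597.5 against 61.6 in B7S1R_SP.

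Haemoglobin genes took 9.72% of the summed FPKM in the TIM-3_SP wild-type library numbered 2, 7.84% in DN and 1.14% in B7S1R_SP, and 0.0136% or less in the libraries labelled KO. Erythroid markers had a median log2 fold change of -9.26 between KO and these wild-type libraries (camera adjusted p = 5.68e-12, and adjusted p = 0.529 with an estimated correlation). B cell markers and stromal and endothelial markers had fewer than 5 measured genes in each comparison.

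Lists that passed in no unblocked comparison of populations were CD4 and regulatory T cell markers and NK cell markers and ribosomal proteins. Their medians were -0.05, -0.01 and -0.38 between TIM-3_SP and DN, with camera adjusted p-values of 0.987, 0.169 and 0.474. In TIM-3_SP against DN, glycolysis (-0.02), oxidative phosphorylation (0.08), tissue residency (-0.58) and costimulatory receptors (-0.53) did not pass either. Between genotypes, tissue residency (-1.01, camera adjusted p = 0.282) and NK cell markers (-0.71, 0.498) did not pass.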
